A study of Xenopus laevis with 4 samples.

How the data were processed

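Presumptive ectoderm of Xenopus laevis was the tissue. Embryos were injected with synthetic mRNA at the 2-cell stage, per the labels' protocols, with ICD alone or with ICD and MCI-HGR. The labels give the names ICD and MCI-HGR; that ICD is the Notch intracellular domain and that HGR is the hormone-binding domain of the glucocorticoid receptor, which holds a fused protein inactive until dexamethasone is added, is background knowledge. Explants were taken at stage 9 to 10, dexamethasone was added at stage 11.5, and RNA was collected 5 h later. There were 4 one-colour Affymetrix arrays, 2 per group.

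The authors deposited 1 signal intensity per probe set and array, on a linear scale, made with MAS5 per the submitters' processing notes; the version and the scaling target are not given in the sources used here. The mean over probe sets, with 2% trimmed from each end, was 204 for ICD replicate 1, 199 for ICD replicate 2, 208 for MCI-HGR replicate 1 and 207 for MCI-HGR replicate 2, and no further scaling was applied in the primary fit. Detection calls and probe-level values were not used here. MAS5 treats each array alone, so array-wide differences in signal distribution remain in the values, and low signals carry a large relative error. The number of arrays limits the precision.

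The 96 control probe sets were left out, and log2 was taken of the 32539 remaining signals, all above 0. Probe sets in the lowest 25% by mean log2 signal, below a signal of about 10.6, were removed, which left 24404. Gene names came from the platform annotation supplied with the values: 15495 probe sets had 1 gene symbol, 279 had several and 16765 were unnamed here. Of 15505 annotated probe sets with 1 symbol, controls included, 15394 had a gene identifier in the RefSeq gene table of assembly v10.1, which updated 2 symbols and was used for names only. Symbols ending in .L and .S are the homeologs of the long and short subgenomes, and near-identical homeologs can share probes. Each of 9380 genes was represented by its probe set of highest mean signal; 2089 genes had more than 1 kept probe set, and the mean over them was an alternative.

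Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), two-sided, with Benjamini-Hochberg adjustment at 0.05 over all genes or over all probe sets. The primary fit had the group as its one term and 2 residual degrees of freedom; its SE is the one printed with log2 differences. A fit with the replicate number as a block (1 residual degree of freedom, with a prior of 15.1 degrees of freedom from all genes) was planned as an alternative. It is printed beside the primary fit because the arrays parted by number in their signal distributions. The labels do not state that the numbers mark a shared clutch or day, and nothing says that replicates came from separate clutches, so p-values measure only the spread between these samples. Blocked refers to that fit and unblocked to the primary fit.

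The 16 gene lists were fixed before the data were examined: multiciliated cell regulators, centrioles and basal bodies, motile axoneme, intraflagellar transport and the Bardet-Biedl complex, tubulins, DNA replication, mitosis, Notch pathway, ionocytes, secretory cells, basal cells and keratins, neural, mesoderm with crest and endoderm, glucocorticoid response, p53 and stress, and ribosomal proteins. Each was tested with camera at a preset correlation of 0.01 and adjusted over the 16 lists, with camera at an estimated correlation and fry as alternatives. Unless the block is named, list tests of the groups were made without it. An estimated correlation then rests on 2 residual degrees of freedom, and the power of that form of camera was not tested. Per list, genes were also adjusted over the list alone. List genes are not independent of each other.

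Named genes followed a rule fixed before the data were examined: beside mcidas, the genes with the largest changes among those that passed, and up to 4 genes per list that passed. As none passed unblocked, the rule fell back to the 5 with the smallest p in each direction and the 2 with the smallest p in each list; 326 uninformative locus symbols were skipped, 10 of them among genes at an unadjusted p of 0.05. Background was judged, by a choice made after the data were seen, from the highest of 17 tag control probe sets of each array, which was 13 and 10 on the ICD arrays and 12.4 and 9.2 on the MCI-HGR arrays. A gene not above it on both arrays of a group is given as at least the fold of the brighter group's mean over that level. For mcidas.S, gsc.S and gli2.L, with 1 array not above it, that array was set to it.

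The fits were tested on simulated data drawn from the 4 arrays' spread over 24404 probe sets, with 50 changed at each of 4 sizes. Where simulated arrays shared a set difference, the unblocked fit recovered 0, 0, 4 and 5 of 50 at log2 changes of 1, 2, 3 and 4, and the blocked fit 35, 50, 50 and 50, with 13 false calls in all. Without a shared difference the unblocked fit recovered 31, 48, 50 and 50, with 12 false calls. The simulated set difference was the same in both groups, and the noise came from the blocked fit, independent between probe sets. The model of the blocked fit thus held by construction, so the simulation cannot decide which fit suits the real arrays. Alternatives covered quantile normalization, median centring, no low-signal filter, removal of the lowest 50%, a floor at the 20th percentile, an offset of the 10th percentile, eBayes without trend or robust, the replicate block, the mean over probe sets, a threshold of 10%, the set tests, and each array left out in turn. Chromosome positions are not printed, as no genome build is named for the deposited values. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.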

Results

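Gene expression was measured in presumptive ectoderm of Xenopus laevis embryos on 4 one-colour Affymetrix Xenopus arrays, 2 per group. All embryos had been injected at the 2-cell stage with synthetic mRNA for ICD, the usual name in this field for the intracellular domain of Notch, which keeps ectodermal cells from forming multiciliated cells. The second group also received mRNA for MCI-HGR, a hormone-inducible form of multicilin, a coiled-coil nuclear regulator of multiciliated cell formation. Explants of both groups were given dexamethasone at stage 11.5 and collected 5 h later, near stage 14. Each array reported 32539 probe sets besides controls, with a median signal of 45.4 and 37.6 on the ICD arrays and 44.2 and 37.1 on the ICD with MCI-HGR arrays. The arrays that shared a replicate number had like signal distributions, and their 99th percentiles were 4167 and 4254 for number 1 and 4979 and 4999.8 for number 2. The ratio of the middle to the 3' actin control probe set was 0.64 and 0.652 on the ICD arrays and 0.569 and 0.401 on the ICD with MCI-HGR arrays, and the 5' to 3' ratio of the Dap control was 0.062 and 0.0646 on the ICD arrays and 0.0415 and 0.028 on the others. The arrays that shared a number are called array set 1 and array set 2 below, and each set held 1 array of each group. The number of arrays limits the precision of every value.

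The comparison asked which genes respond to multicilin activity when Notch signalling is held on. With MCI-HGR and the array set as a block, 8 of 14 regulators of multiciliated cell formation, 31 of 50 genes of centrioles and basal bodies and 54 of 55 genes of the motile axoneme rose. By camera with the block and the preset correlation these lists had an adjusted p = 1.01e-17, 7.61e-27 and 4.43e-107. Without the block, the estimated correlations of these lists were 0.462, 0.0597 and 0.463, above the preset 0.01. With them camera gave an adjusted p = 0.331, 0.177 and 0.18. A typical axoneme gene was 4.89-fold higher, and tsga10.L and tekt2.S, which had the largest rises among the genes named by rule, were 24.8-fold and 22.4-fold higher. Genes of DNA replication had a median log2 difference of -0.27. Without the block, 0 of 77 passed an adjusted p of 0.05 over the list alone. The list then had an adjusted p = 1.02e-13 by camera at the preset correlation and 0.331 with an estimated correlation. With the array set as a block, both tp63 homeologs and 5 hes5 genes fell and both hes1 homeologs rose, while hes5.1.L did not pass. The control ratios for RNA ends given above were lower with MCI-HGR in both array sets, and so ran with the group beside every gene list. Among 9380 genes, limma without a block called 0 in either direction at an adjusted p of 0.05 (smallest adjusted p = 0.0516), while 343 genes were higher and 42 lower at an unadjusted p of 0.05. With the array set as a block, 630 genes rose and 311 fell, of which 294 rose and 40 fell at least 2-fold. Rose and fell are used for genes that passed with the array set as a block, or, where stated, adjusted over a list alone without it; the fold of each gene is that of the group means on the log2 scale. Genes given without an adjusted p were chosen after their values were seen, and the other genes by a rule fixed before.

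Multicilin itself was read by 1 probe set (mcidas.S, probe set Xl2.55698.1.S1_at). Its signal was 9.7 and 17.1 on the ICD arrays and 384.2 and 141.5 on the arrays with MCI-HGR, a log2 difference of 4.18 ± 0.61 as read (SE, n = 2 per group). By the group means this was at least 15.6-fold, with the ICD array of set 1 set to its highest tag control. Multicilin rose at least 29.6-fold in set 1, with the ICD array set to its highest tag control, and 8.28-fold in set 2 (limma, adjusted p = 1.89e-11 with the set as a block, 0.172 without). Without the block it passed once either ICD array was left out, at adjusted p = 0.0204 and 0.0163 in fits with a lone ICD array, and not without MCI-HGR replicate 1 or 2, at 0.201 and 0.157. Its log2 difference was then 3.46 and 4.90. The ICD value of set 1 lay below the highest of the 17 tag control probe sets of that array, which was 13. Whether the probe set reads the injected mRNA, the embryo's own transcript or both is not known here.

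Of 14 measured genes on the list of multiciliated cell regulators, which includes mcidas, 7 rose and 0 fell when adjusted over the list alone, and 8 rose with the array set as a block. The forkhead factor foxj1, which switches on genes of motile cilia, rose in both homeologs, the .L and .S copies of a gene that this allotetraploid frog carries: foxj1.S went from 276 ± 10.1 to 3244 ± 814 (signal, mean ± SD, n = 2), 11.6-fold by the group means, 13.5-fold in set 1 and 9.93-fold in set 2 (limma, adjusted p = 6.89e-21 blocked, 0.0651 unblocked), and foxj1.L rose 7.2-fold. The related foxj1.2.L rose 17.1-fold. The cyclin-like gene ccno, needed for centriole amplification, rose 16.3-fold for ccno.L (23.5-fold in set 1 and 11.2-fold in set 2; limma, adjusted p = 3.45e-19 blocked, 0.0654 unblocked) and 27.2-fold for ccno.S. The forkhead gene foxn4.S rose 10.7-fold and the ciliary regulator rfx2.S 3.15-fold. Genes for partners in the transcription complex that multicilin joins stood still within error: e2f4.S had a log2 difference of -0.028 ± 0.21 and tfdp1.L one of 0.021 ± 0.17 (SE, n = 2 per group), and neither passed. The median log2 difference of the list was 2.25 (2.18 in set 1 and 2.32 in set 2; camera, adjusted p = 2.72e-15); with an estimated correlation the adjusted p = 0.331.

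**Figure D1:**
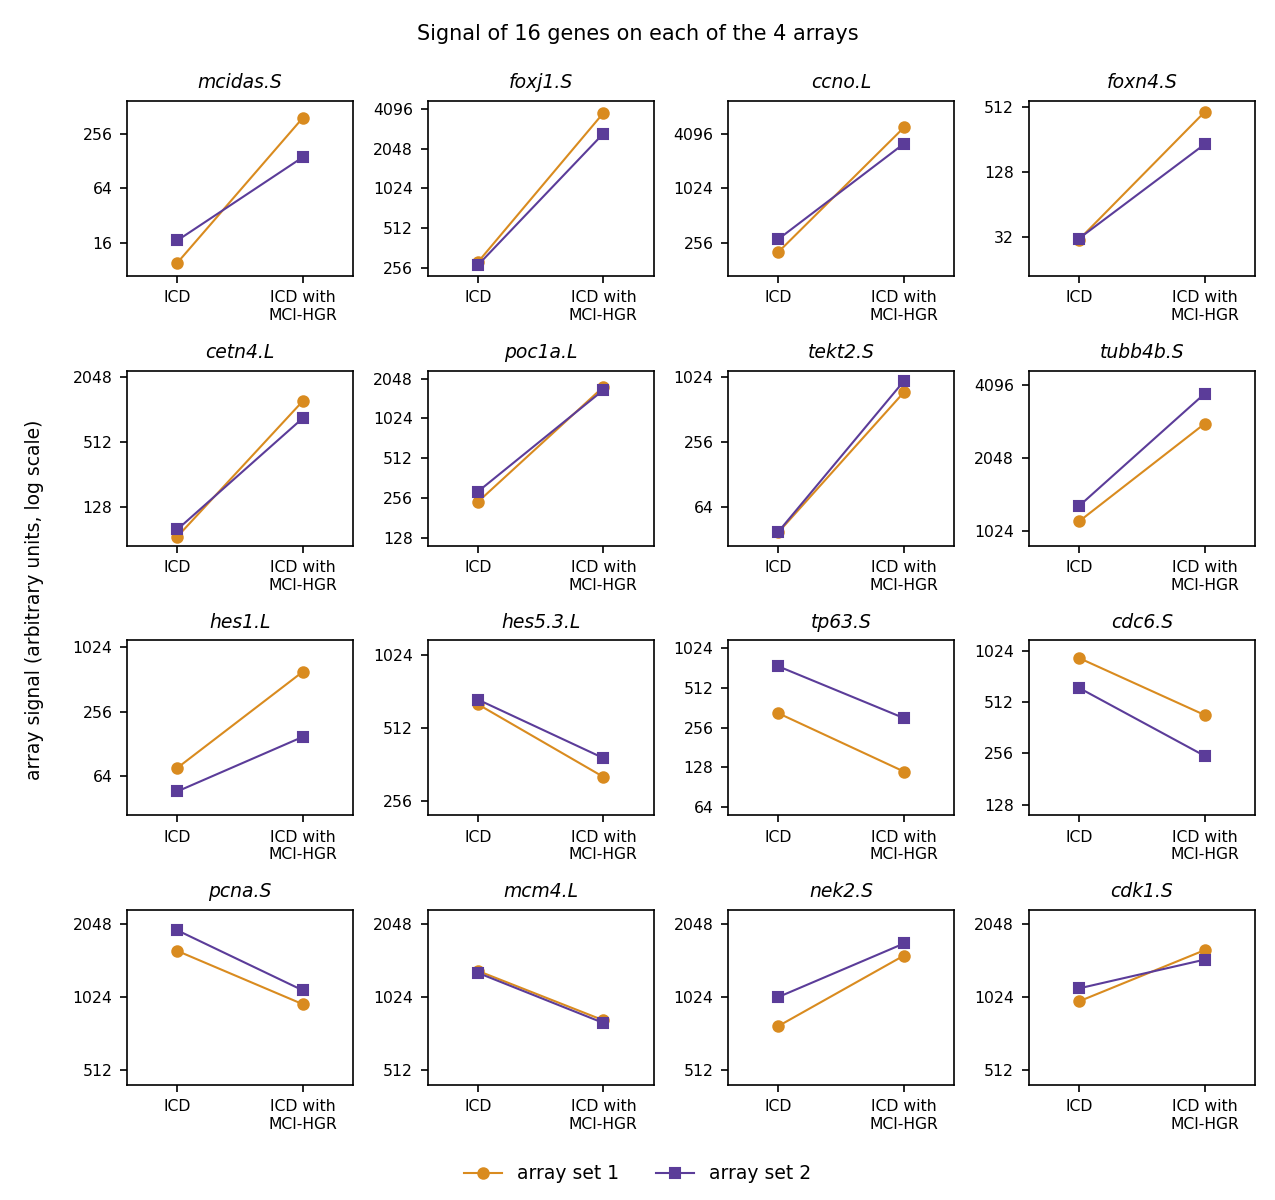
Array signal in arbitrary units on a log axis for 16 genes, with the ICD array on the left and the ICD with MCI-HGR array on the right of each panel; orange circles are array set 1 and purple squares array set 2, with a line joining the arrays of a set. foxj1.S was 283 and 268.7 without MCI-HGR and 3819 and 2668 with it, while cdc6.S, pcna.S and mcm4.L were lower with MCI-HGR in both sets.

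Centrioles multiply in multiciliated cells to make the basal bodies of many cilia. Of 50 measured genes on the list of centriole assembly and basal bodies, 18 rose and 0 fell adjusted over the list alone, and 31 rose and 0 fell with the array set as a block. The centriole wall protein gene poc1a.L rose from 262 ± 33.2 to 1725 ± 67.4 (6.62-fold, 7.44-fold in set 1 and 5.88-fold in set 2; limma, adjusted p = 4.23e-18 blocked, 0.0654 unblocked). The centrin gene cetn4.L rose from 72.9 ± 7.92 to 1039.8 ± 266 (14.1-fold, 18.2-fold in set 1 and 10.8-fold in set 2; limma, adjusted p = 5.58e-18 blocked, 0.0654 unblocked). ccdc78.S, a component of the deuterosome on which many centrioles form, rose 9.52-fold, and cep152.L, which recruits the centriole duplication kinase, rose 4.89-fold. The gene of that kinase, plk4.L, rose 1.45-fold and sass6.L, of the cartwheel of the forming centriole, 1.52-fold. Among the 19 that did not pass were cep192.L and tubg1.L, of the pericentriolar material, with log2 differences of 0.055 ± 0.22 and -0.034 ± 0.47 (SE, n = 2 per group). The other homeolog, tubg1.S, rose, with a log2 difference of 0.76. The median log2 difference of the list was 0.85 (0.61 in set 1 and 0.98 in set 2; camera, adjusted p = 7.32e-26), and the adjusted p = 0.177 with an estimated correlation.

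The axoneme, the microtubule core of a motile cilium, gave the list with the largest share of genes that rose. All 55 measured genes of the motile axoneme list were higher with MCI-HGR in both sets, 52 rose adjusted over the list alone, and 54 rose with the array set as a block. The exception was gas8.S, at 21 and 17.9 without MCI-HGR and 23.3 and 49.3 with it. The tektin gene tekt2.S rose from 37.2 ± 0.354 to 842 ± 142 (22.4-fold, 20.05-fold in set 1 and 25.1-fold in set 2; limma, adjusted p = 2.59e-19 blocked, 0.0516 unblocked), and the dynein assembly gene zmynd10.L from 121 ± 13.4 to 746 ± 18.2 (6.17-fold, 5.61-fold in set 1 and 6.79-fold in set 2; limma, adjusted p = 8.24e-16 blocked, 0.0796 unblocked). The rises ran down to 1.48-fold for spata17.L, and cfap52.S rose 16.1-fold and cfap52.L 3.15-fold. The dynein light chain gene dnal1.L rose 8.24-fold and the radial spoke gene rsph9.L 3.84-fold. The median log2 difference was 2.29, or 2.19 with genes near background set to their bounds (1.83 in set 1 and 2.55 in set 2; camera, adjusted p = 3.07e-101); with an estimated correlation the adjusted p = 0.18.

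The 5 genes with the smallest p among those higher included 3 outside the lists. The testis gene tsga10.L rose from 52.8 ± 8.42 to 1300.4 ± 1.34 (24.8-fold, 22.1-fold in set 1 and 27.8-fold in set 2; limma, adjusted p = 7e-21 blocked, 0.0516 unblocked). saxo2.L, of a family of axonemal microtubule stabilizers, rose from 61.0 ± 12.5 to 1055 ± 131 (17.4-fold; limma, adjusted p = 8.76e-20 blocked, 0.0651 unblocked). The alpha-tubulin gene tuba1cl.3.L, already bright without MCI-HGR, rose from 2115 ± 146 to 11379 ± 249 (5.39-fold, 5.57-fold in set 1 and 5.21-fold in set 2; limma, adjusted p = 1.93e-21 blocked, 0.0516 unblocked). The other 2 were foxj1.S and tekt2.S.

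Intraflagellar transport carries parts along the cilium, and the Bardet-Biedl complex moves membrane proteins. Of 31 measured genes of this list, 16 rose and 0 fell adjusted over the list alone, and 25 rose and 0 fell with the array set as a block. rabl2b.S rose from 64.9 ± 11 to 335 ± 53.3 (5.17-fold; limma, adjusted p = 5.22e-12 blocked, 0.131 unblocked) and hspb11.L from 148 ± 16.1 to 670.5 ± 175 (4.47-fold; adjusted p = 5.39e-14 blocked, 0.143 unblocked, limma). bbs12.L rose 9.49-fold and ift80.L 3.21-fold. The median log2 difference was 1.01 (0.73 in set 1 and 1.19 in set 2; camera, adjusted p = 2.85e-29), and with an estimated correlation the adjusted p = 0.177. Most of the 20 measured genes of tubulins and tubulin modification did not pass: tubb4b.S rose adjusted over the list alone and 5 genes rose with the block. Those 5 were the beta-tubulin genes tubb4b.S (2.71-fold; limma, adjusted p = 1.22e-14 blocked, 0.16 unblocked) and tubb4b.L (1.48-fold), the glutamylase gene ttll1.S (2.87-fold; limma, adjusted p = 4.31e-08 blocked, 0.484 unblocked), the deglutamylase gene agbl5.L (2.10-fold) and tuba4b.L (1.38-fold). The median of that list was 0.11 (camera, adjusted p = 0.016), and the adjusted p = 0.331 with an estimated correlation. It turned to -0.082 without ICD replicate 2 (adjusted p = 0.241) and was 0.048 without MCI-HGR replicate 1 (adjusted p = 0.107).

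**Figure D2:**
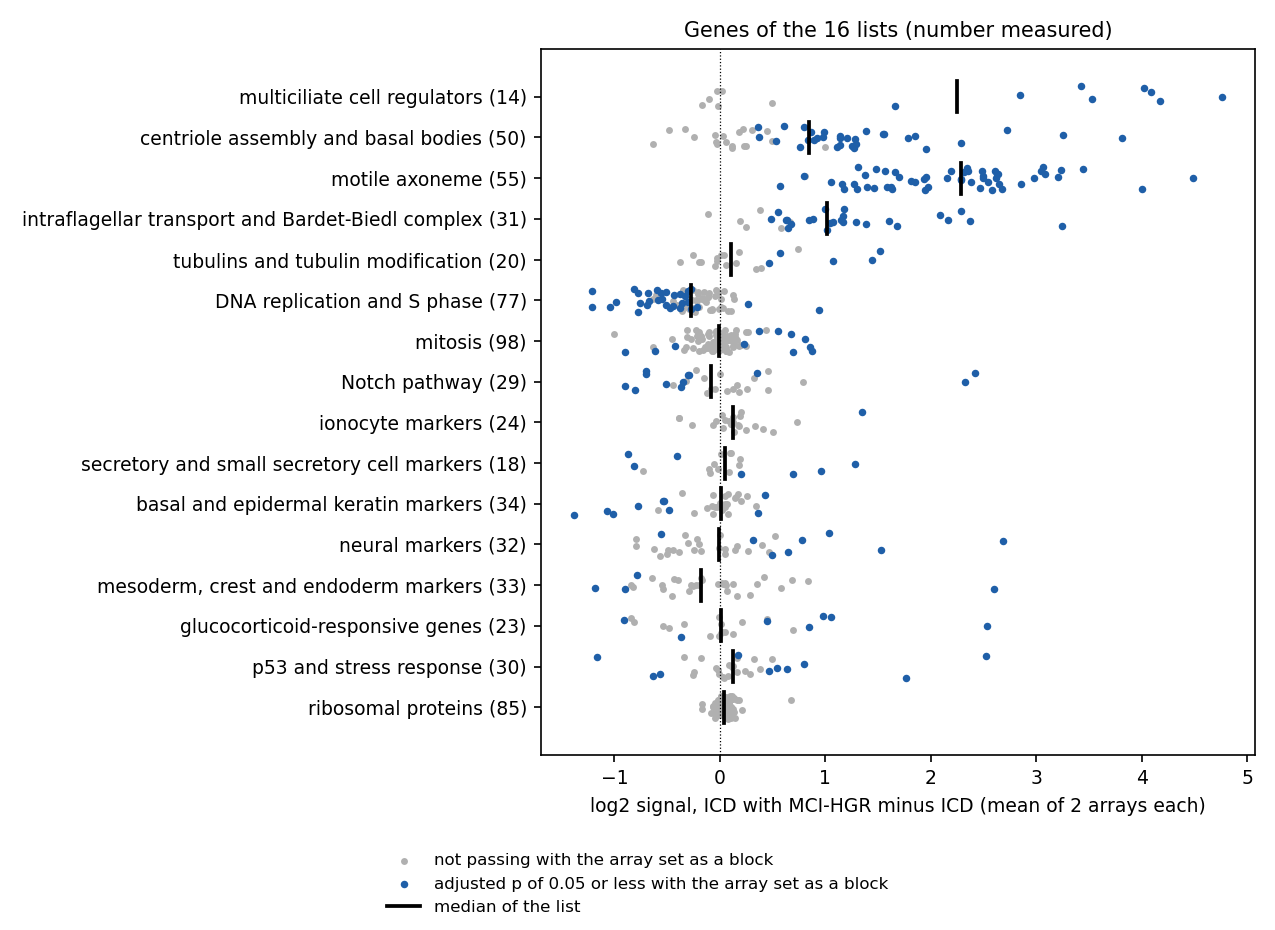
Log2 signal of the ICD with MCI-HGR arrays minus the ICD arrays (means of 2 arrays each) for each measured gene of the 16 lists, with the number of genes in brackets; blue points passed an adjusted p of 0.05 with the array set as a block, grey points did not, and black bars are medians. The axoneme points all lie above 0 with a median of 2.29, while the DNA replication list has a median of -0.27 and the mitosis list one of -0.0048.

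Genes of DNA replication went the other way. Of 77 measured genes of that list, 60 were lower in both sets and 5 higher in both; 29 fell and 2 rose with the array set as a block, and 0 passed adjusted over the list alone. mcm4.L, of the replicative helicase, fell from 1305 ± 17.4 to 813 ± 14.6 (1.61-fold lower, 1.60-fold in set 1 and 1.61-fold in set 2; limma, adjusted p = 5.69e-07 blocked, 0.424 unblocked), and pcna.S, the sliding clamp of the polymerase, from 1765 ± 244 to 1026 ± 95.4 (1.72-fold lower, 1.66-fold in set 1 and 1.77-fold in set 2; limma, adjusted p = 1.83e-08 blocked, 0.478 unblocked). The largest falls on the list were of the licensing gene cdc6.S (2.32-fold) and of e2f1.L (2.31-fold), a driver of S phase, and the cyclin E gene ccne2.S fell 1.97-fold. The median log2 difference was -0.27 (-0.25 in set 1 and -0.29 in set 2; camera, adjusted p = 1.02e-13), and with an estimated correlation the adjusted p = 0.331. It was -0.13 without ICD replicate 1, -0.14 without MCI-HGR replicate 2, -0.46 without ICD replicate 2 and -0.49 without MCI-HGR replicate 1. Of 98 measured mitosis genes, 8 rose and 3 fell with the block and 0 passed adjusted over the list alone. nek2.S, a centrosomal kinase, rose 1.8-fold (limma, adjusted p = 9.72e-09 blocked, 0.497 unblocked), the anaphase activator cdc20.L 1.59-fold (limma, adjusted p = 7.19e-07 blocked, 0.597 unblocked), cdk1.S 1.46-fold and ccna1.S 1.83-fold; fbxo5.L, an inhibitor of the anaphase-promoting complex, fell 1.53-fold. The median of the mitosis list was -0.0048 and became 0.024 with each array centred on its median (camera, adjusted p = 0.504, and 0.863 with an estimated correlation).

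The Notch list split by gene. Of 29 measured genes, 3 rose and 9 fell with the array set as a block, and 0 passed adjusted over the list alone. The repressor gene hes1 rose in both homeologs, 5.02-fold for hes1.L (7.83-fold in set 1 and 3.22-fold in set 2) and 5.37-fold for hes1.S (8.86-fold in set 1 and 3.25-fold in set 2; limma, adjusted p = 9.71e-09 blocked, 0.672 unblocked). By contrast hes5.3.L fell from 654 ± 20.6 to 352 ± 44.5 (1.87-fold lower, 2.00-fold in set 1 and 1.74-fold in set 2; limma, adjusted p = 1.96e-07 blocked, 0.398 unblocked), hes5.6.L fell 1.74-fold and hey1.S 1.62-fold; hes1, hes5 and hey1 all belong to the families of Notch target genes. The log2 difference of hes1.S was 1.5 without MCI-HGR replicate 1 and 3.35 without MCI-HGR replicate 2. The median log2 difference was -0.080 (-0.23 in set 1 and 0.012 in set 2) and the mean was 0.056, of opposite sign. By camera the adjusted p = 0.161, 0.0353 with the block, 0.0638 with block and quantile normalization, and 0.721 with an estimated correlation and no block. With 1 array left out the median ran from -0.42 without ICD replicate 2 (adjusted p = 0.00101) to 0.24 without ICD replicate 1 (adjusted p = 0.387).

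Of 24 ionocyte genes, ubp1.L alone rose with the block and 0 fell (2.54-fold; limma, adjusted p = 0.00735 blocked, 0.922 unblocked). The mean over the 2 probe sets of ubp1.L gave a log2 difference of 0.42 in place of 1.35. The gene atp6v1h.L, of the proton pump, had a log2 difference of 0.50 ± 0.36 and did not pass (limma, adjusted p = 0.0899 blocked). Of 18 genes of secretory and small secretory cells, 4 rose and 3 fell with the block: grhl3.S, an epidermal transcription factor, rose 2.44-fold (3.31-fold in set 1 and 1.79-fold in set 2; limma, adjusted p = 2.8e-09 blocked, 0.368 unblocked), grhl3.L rose 1.62-fold (limma, adjusted p = 3.03e-05 blocked, 0.957 unblocked), and ag1.S and agr2.L, genes of the mucus-secreting cement gland, fell 1.83-fold and 1.76-fold. Of 34 genes of basal cells and epidermal keratins, 2 rose and 7 fell with the block. tp63.S, the master regulator of basal epidermal cells, fell from 537 ± 295 to 211 ± 129.8 (2.61-fold lower, 2.76-fold in set 1 and 2.46-fold in set 2; limma, adjusted p = 5.48e-10 blocked, 1 unblocked), tp63.L fell 2.02-fold, and the desmosome gene dsp.L fell 2.10-fold (limma, adjusted p = 0.00416 blocked, 1 unblocked). With 1 array left out, the log2 difference of tp63.S ran from -2.06 without MCI-HGR replicate 2 to -0.71 without MCI-HGR replicate 1, and that of dsp.L from -1.49 to -0.64 in the same order. None of the 3 lists passed adjusted over the list alone for any gene, and their median log2 differences were 0.13, 0.049 and 0.011, with camera adjusted p = 0.167, 0.359 and 0.106. The mean of the basal and keratin list was -0.14 and camera pointed down, against its median, which turned to -0.035 after quantile normalization. The secretory median was -0.14 without ICD replicate 1 (camera, adjusted p = 0.0307) and 0.15 without ICD replicate 2 (0.00184), and the basal and keratin median was -0.29 (4.59e-05) and 0.039 (0.373) in the same order.

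Of 32 neural genes, 7 rose and 1 fell with the block. six3.L, of the anterior neural plate, was not above the highest tag control on both ICD arrays and rose at least 3.58-fold (limma, adjusted p = 4.76e-06 blocked, 0.215 unblocked); sox2.L rose 2.05-fold, and ncam1.L rose 1.56-fold (limma, adjusted p = 0.00947 blocked, 1 unblocked). Of 33 genes of mesoderm, crest and endoderm, 1 rose and 3 fell with the block: gsc.S, of the organizer, rose at least 5.67-fold with 1 of its 2 ICD arrays below the tag controls and set to the highest of them (limma, adjusted p = 4.82e-08 blocked, 1 unblocked), and snai1.S fell 2.27-fold (limma, adjusted p = 0.000105 blocked, 1 unblocked). The homeolog gsc.L, close to the tag controls at 8.7 and 10.4 without MCI-HGR and 13.5 and 12 with it, did not pass. With 1 array left out the log2 difference of gsc.S ran from 1.43 without MCI-HGR replicate 1 to 3.76 without MCI-HGR replicate 2. Without ICD replicate 1 and without MCI-HGR replicate 2 it was -0.65 for snai1.S in both cases, and 0.37 and 0.34 for ncam1.L. The mesodermal gene tbxt.S read 930.4 and 474.1 on the set 1 arrays without and with MCI-HGR, and 12 and 25.8 on the set 2 arrays. In the same order the endomesoderm gene vegt.S, outside the lists, read 1221 and 627 in set 1, and 18.4 and 26.9 in set 2. Mesodermal signal in set 1 thus also differed between the groups for tbxt.S and vegt.S, with 1 array per group. The notochord gene not, also outside the lists, fell 2.13-fold for not.L and 2.51-fold for not.S. The neural median was -0.0035 with a mean of 0.090, and the sign of the median turned with median centring, to 0.026 (camera, adjusted p = 0.785). The median of the mesoderm, crest and endoderm list was -0.18 (camera, adjusted p = 0.2). Neither list had a gene that passed adjusted over the list alone.

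Dexamethasone was given to both groups, so its own targets are not what the comparison tests. Of 23 glucocorticoid-responsive genes, 5 rose and 2 fell with the block, among them ddit4.S (1.97-fold; limma, adjusted p = 6.74e-10 blocked, 0.573 unblocked), errfi1.S (2.07-fold; limma, adjusted p = 0.00941 blocked, 0.939 unblocked) and cebpb.L (2.46-fold in set 1 and 13.7-fold in set 2). Their median was 0.012 and turned to -0.034 after quantile normalization (camera, adjusted p = 0.504). Of 30 genes of the p53 and stress response, 7 rose and 3 fell with the block. The heat shock gene hsp70.L rose from 95.8 ± 54.4 to 505 ± 35.3 (5.75-fold, 9.25-fold in set 1 and 3.58-fold in set 2; limma, adjusted p = 1.96e-11 blocked, 0.27 unblocked), gadd45a.S rose 1.38-fold (limma, adjusted p = 3.85e-06 blocked, 0.754 unblocked) and jun.L rose 3.39-fold. The mean over its 4 probe sets gave gadd45a.S a log2 difference of 0.72 in place of 0.46. The log2 difference of hsp70.L was 1.91 without ICD replicate 1 and 3.14 without ICD replicate 2. The median of that list was 0.12 (camera, adjusted p = 0.0233), a call that ended with the block, at 0.083, and with an estimated correlation, at an adjusted p = 0.355, and without ICD replicate 1 (0.19), ICD replicate 2 (0.0873) or MCI-HGR replicate 1 (0.197). None of the genes of these 2 lists passed adjusted over the list alone. Of 85 ribosomal protein genes 0 passed in either fit, with a median of 0.042 and log2 differences from -0.17 to 0.68 (camera, adjusted p = 0.504). rps3a.S and rps15.S, the members with the smallest p, had log2 differences of 0.16 ± 0.14 and 0.68 ± 0.60 and did not pass (limma, adjusted p = 0.0834 and 0.15 blocked). The ribosomal median was -0.21 without ICD replicate 1 and 0.31 without ICD replicate 2 (camera, adjusted p = 3.82e-10 and 1.88e-13).

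Fewer genes fell than rose with the block, 40 against 294 at 2-fold or more. The 5 genes with the smallest p among those lower were ptn.L, gli2.L, rexo1.S, hes5.3.L and mcm4.L. The growth factor gene ptn.L fell from 3450.2 ± 81.0 to 2076 ± 159.6 (1.66-fold lower; limma, adjusted p = 3.38e-09 blocked, 0.315 unblocked). The mean over its 2 probe sets gave a log2 difference of -0.18 in place of -0.73. The hedgehog pathway gene gli2.L fell from 46.2 ± 14.5 to 10.1 ± 1.56 (at least 3.82-fold lower, with 1 of its 2 MCI-HGR arrays below the tag controls and set to the highest of them; limma, adjusted p = 3.39e-05 blocked, 0.323 unblocked). The exonuclease gene rexo1.S fell from 454 ± 8.42 to 231 ± 8.48 (1.96-fold lower; limma, adjusted p = 2.81e-07 blocked, 0.329 unblocked).

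Over all 9380 genes, 3066 were higher and 2718 lower in both array sets, 32.7% and 29.0%, where 25% each would follow from independent signs, and the log2 differences of the sets correlated at a Pearson r of 0.614 across genes, which are not independent replicates. Of the 16 lists, 7 passed with camera at its preset correlation, and 0 passed with a correlation estimated from these 4 arrays, the adjusted p then running from 0.177 to 0.907. Estimated correlations ran from -0.00882 for the glucocorticoid list to 0.823 for the ribosomal list, against the preset 0.01. Those of the axoneme and regulator lists, 0.463 and 0.462, lay far above it. If these estimates hold, camera at the preset value gave those lists too small a p. The difference between the array sets was not taken out of the estimates. With 2 residual degrees of freedom and untested power, the estimated form cannot decide whether a list moved. Even the axoneme list, with all 55 genes higher in both sets, had an adjusted p = 0.18 by this form of camera. With 2 arrays per group, the count of called genes rests on whether the difference between the array sets is taken out. Without the block, limma called 73 genes higher when ICD replicate 1 was left out, 55 when ICD replicate 2 was left out, and 0 when either MCI-HGR array was left out.

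**Figure D3:**
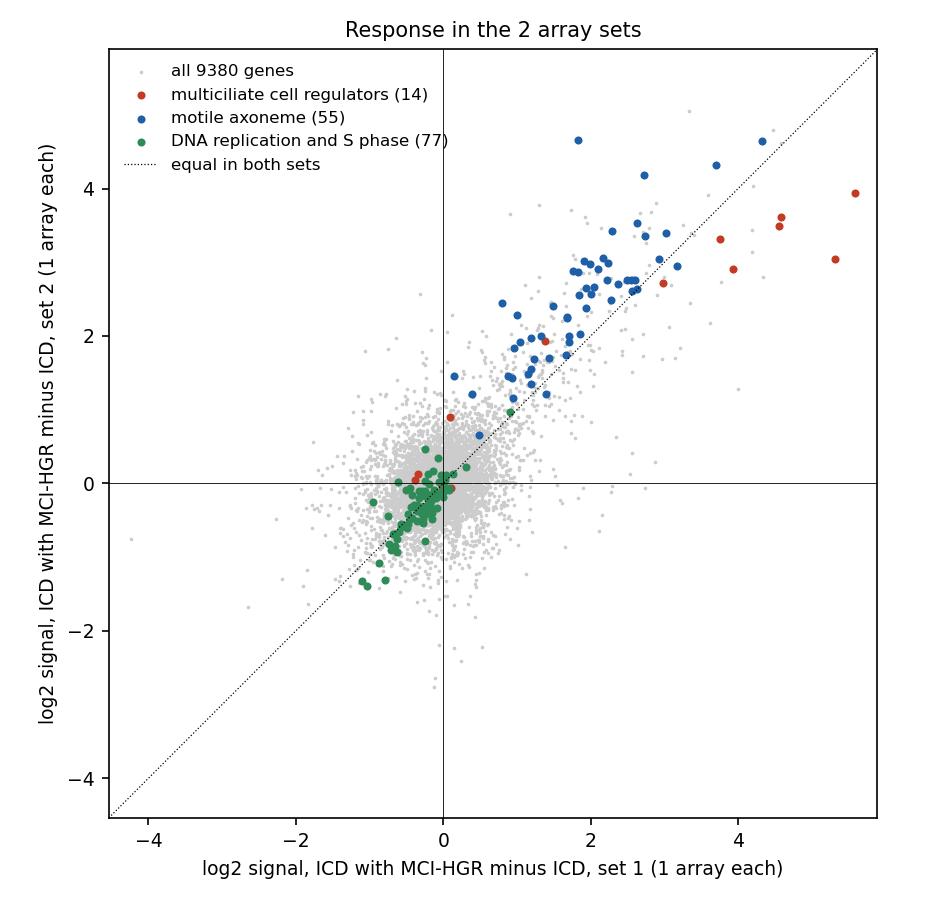
Log2 signal of ICD with MCI-HGR minus ICD within array set 1 (x axis) and within array set 2 (y axis), 1 array per group in each, for all 9380 genes in grey and for the regulator, axoneme and DNA replication lists in colour; the dotted line marks equal values. All 55 axoneme genes lie above 0 in both sets, and the highest regulator genes lie below the line of equal values.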

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

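The replicate block with quantile normalization was chosen after seeing the data; the other alternatives were planned. The block moved the counts most. Arrays of one number deviated together: the difference between array 2 and array 1 correlated between the groups at r = 0.745 across probe sets, which are not independent, and splitting the 4 arrays by number called 2286 genes, by group 0, and by the crossed split 0. Arrays of one number thus shared a deviation. With only 2 pairs and no label that says what the numbers mark, what these arrays shared is not known. Without the block the median residual SD was 0.34 on the log2 scale, and with it 0.12. The replicate block called 630 genes higher and 311 lower (294 and 40 at least 2-fold), and 1142 probe sets higher and 551 lower. With quantile normalization as well, the counts were 486 and 278 genes (275 and 41 at least 2-fold) and 982 and 518 probe sets. Unblocked, 2 genes were higher after quantile normalization, 3 without the low-signal filter, 3 with the floor and 3 with the mean over probe sets, all at least 2-fold, and 13 at an adjusted p of 10%; the cause was not tested. With 1 array left out, where the lone array is assumed to vary like the other group, 0 to 73 genes were higher (0 to 73 at least 2-fold) and 0 to 126 probe sets. The other 65 counts were 0, as without any change of setting. The unblocked fit recovered few simulated changes where the sets differed, in a simulation built on the model of the blocked fit.

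The camera call of each list that passed ended with an estimated correlation and with fry, at unmoved medians, with adjusted p for each test in that order: regulators 2.25 (0.331 and 0.143), centriole genes 0.85 (0.177 and 0.0966), axoneme genes 2.29 (0.18 and 0.0914), intraflagellar transport genes 1.01 (0.177 and 0.0914), tubulins 0.11 (0.331 and 0.834), DNA replication genes -0.27 (0.331 and 0.834), p53 and stress genes 0.12 (0.355 and 0.345). Over all other alternatives the highest adjusted p of the regulator, centriole, axoneme and intraflagellar lists was 3.47e-11. The p53 and stress list also fell short without the filter (0.12; adjusted p = 0.0531), with the block (0.12; 0.083) and with block and quantile normalization (0.093; 0.0651). The Notch list passed by camera with the lowest 50% left out (median -0.23, adjusted p = 0.0156) and with the block (-0.080, adjusted p = 0.0353). It did not pass with block and quantile normalization (-0.12, adjusted p = 0.0638). The mesoderm, crest and endoderm list (-0.27, adjusted p = 0.0195) and the basal and keratin list (-0.027, adjusted p = 0.0354) passed by camera with the lowest 50% left out. Medians near 0 turned sign: mitosis to 0.024 (median centring) and 0.0029 (lowest 50% left out); basal cells and keratins to -0.035 (quantile, with or without block), -0.027 (lowest 50% left out) and -0.034 (mean over probe sets); neural to 0.026 (median centring), 0.025 (no filter, and floor), 0.073 (lowest 50% left out) and 0.014 (mean over probe sets); glucocorticoid response to -0.034 (quantile, with or without block). The causes were not tested. List medians kept direction and side of the threshold in 211 comparisons and turned sign in 31.

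Leaving out 1 array leaves the array sets unequal between the groups. Median log2 differences then ranged, for the lists in turn, as follows: regulators 1.75 to 2.75, centriole genes 0.64 to 0.96, axoneme genes 1.98 to 2.36, intraflagellar transport genes 0.87 to 1.15, DNA replication genes -0.49 to -0.13, tubulins -0.082 to 0.41, mitosis -0.10 to 0.081, Notch -0.42 to 0.24. For the others they were ionocytes -0.076 to 0.23, secretory cells -0.14 to 0.31, basal cells and keratins -0.30 to 0.059, neural -0.33 to 0.23, mesoderm, crest and endoderm -0.28 to 0.22, glucocorticoid response -0.11 to 0.32, p53 and stress genes 0.070 to 0.24, ribosomal proteins -0.21 to 0.31. Multicilin, with its signals as read, had a log2 difference of 4.18 and passed with the block, and of 3.46 to 4.90 with 1 array left out. Named genes kept direction and side of the threshold in 458 comparisons and passed in 68 where they had not before, 35 of these with the block; rps15.S turned to -0.13 without ICD replicate 1 and was 1.49 without ICD replicate 2. Signals under about 10 lie near the tag controls, where folds are bounds.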

Other observations

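For the comparison of the groups, limma with and without the replicate block, camera, quantile normalization and leaving out 1 array were planned. The other tests in this part were chosen after the results had been seen, as were its genes. Genes outside the fixed lists also responded, by limma with the array set as a block. Several of the strongest bear ciliary names that the lists did not match. Among them were the dynein arm docking gene odad4.L (3.34-fold higher), the dynein assembly gene dnaaf10.L (2.88-fold) and the dynein light chain gene dynlt5.S (5.34-fold). The genes named next were picked for variety and do not stand for the whole response outside the lists. The receptor tyrosine kinase gene kit.S rose 12.7-fold, the ciliary small-GTPase partner arl2bp.L 3.16-fold, the fatty acid elongase gene elovl2.L 10.4-fold, the endothelial transcription factor gene sox7.L 7.45-fold and the kinase gene cdk7.L 3.75-fold (adjusted p = 1.61e-17, 4.31e-16, 4.79e-13, 1.72e-14 and 2.53e-14; unblocked 0.0796, 0.11, 0.118, 0.393 and 0.181). Among genes that fell, the aquaporin gene aqp3.L was 3.14-fold lower, the retinoid-binding gene crabp2.L 1.73-fold and the myelin gene pmp22.L 2.85-fold. rrm2.2.L, of ribonucleotide reductase, was 2.00-fold lower. By limma these genes had in turn an adjusted p = 6.36e-09, 1.44e-08, 2.25e-08 and 1.55e-10 blocked, and 0.489, 1, 0.825 and 1 unblocked. The DNA replication list names rrm2, and rrm2.2.L was not matched to it because of the number in its symbol.

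Homeologs were called together more often than independent calls would give, though in most pairs with a call only 1 member was called. At least 1 member rose in 157 pairs and fell in 116. Of 1609 pairs with both members measured, both rose in 45 pairs, against 6.3 for independent calls (Fisher's exact test, p = 1.14e-31), both fell in 20 against 2.86 (p = 2.88e-13), and calls were opposite in 1; probes shared between near-identical copies add to such counts. Probe sets without a gene name made up 516 of the 1142 that rose with the block, 45.2%, and 47.8% of those tested. The largest, Xl2.51456.1.S1_at, read 13.1 and 92.8 on the ICD arrays and 1808 and 4594 with MCI-HGR, 138-fold and 49.5-fold higher in sets 1 and 2 (limma, adjusted p = 7.79e-12 blocked, 0.243 unblocked).

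Arrays of one replicate number were more alike (Pearson 0.973 and 0.971 across probe sets) than arrays of one group (0.944 and 0.951), and 2662 genes were higher in set 1 and 1903 in set 2 (limma with the group as a block, adjusted p of 0.05), among them the endomesoderm gene vegt.S, at 1221 and 18.4 on the ICD arrays of sets 1 and 2, and the keratin gene krt19.L, at 1248 and 9551. A difference in signal distribution as the whole cause was argued against, since the set differences of the groups still correlated at 0.737 after quantile normalization, against 0.745 before. A constant scaling factor leaves this correlation unchanged, so the comparison does not bear on scaling. An earlier epidermal stage in set 1 stays open: of the called secretory, basal and keratin markers 29 were higher in set 2 and 7 in set 1 (exact sign test, p = 0.000313, adjusted over 2 tests 0.000625), though genes are not independent and dilution by other tissue would give the same. For the set difference the secretory list and the basal and keratin list had an adjusted p = 1.98e-05 and 4.88e-05 by camera at the preset correlation. With an estimated correlation both had 0.663, as had the ribosomal list. That form had 1 residual degree of freedom here and cannot decide. The shift was not particular to these 2 lists, as 76 ribosomal protein genes were higher in set 2 and 1 in set 1. Mesodermal tissue in the set 1 explants stays open, with 12 markers of mesoderm, crest and endoderm higher in set 1 and 5 in set 2 (exact sign test, adjusted p = 0.143). The sign test counts each called marker alike, whatever its size, and so cannot decide this. On the list, tbxt.S and tbxt.L differed most toward set 1. They read 930.4 and 668.9 on the ICD array of set 1, and 12 and 13.2 on that of set 2. The largest difference toward set 2 on the list was of hba3.L, at 20.5 and 100.6 on the ICD arrays of sets 1 and 2. Outside the list, vegt.S was 66.4-fold and vegt.L 22.6-fold higher on the ICD array of set 1, and 23.3-fold and 8.92-fold with MCI-HGR. The muscle gene myog.L went the other way, 11.5-fold and 12.6-fold higher in set 2. Transcripts of tbxt and vegt were thus higher on both set 1 arrays. Whether other tissue or an earlier stage brought them cannot be told apart here.

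Of the genes that rose, 7 of 8 regulators had the larger fold in set 1 and 52 of 54 axoneme genes in set 2, while over all 14 regulators the median log2 difference was 2.18 in set 1 and 2.32 in set 2. Among those that rose, the median of set 2 minus set 1 was 0.56 (log2) for axoneme genes, -0.999 for regulators and -0.97 for regulators without mcidas.S, whose signal with MCI-HGR was 384.2 in set 1 and 141.5 in set 2. A larger fold in set 2 was not particular to axoneme genes. It was found for 22 of 31 centriole genes (median 0.32) and 19 of 25 intraflagellar transport genes (median 0.28) that rose. The 576 genes that rose outside the axoneme list had a median of 0.10. A wider signal range of the set 2 arrays as the whole cause was argued against, as after quantile normalization the axoneme median was 0.40 and the regulator median -1.30. With 1 array per group and set, these differences have no replicate, and whether the sets differed in the amount of injected mRNA stays open, since it is not known whether the mcidas.S probe set reads it.

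The DNA replication list lay lower with MCI-HGR (median log2 -0.27, or -0.49 to -0.13 with 1 array left out; camera, adjusted p = 1.02e-13, and 0.331 with an estimated correlation), and the mitosis list did not. Among genes that passed with the block, 2 replication genes rose and 29 fell, and 8 mitosis genes rose and 3 fell. A brightness-dependent shift between arrays was argued against as the whole cause, since after quantile normalization the list's median was -0.31 and the 2.5th percentile of brightness-matched random lists -0.067. The replication list also differed between the array sets, with 42 genes higher in set 1 and 7 in set 2. For that difference camera gave an adjusted p = 0.000813 at the preset correlation and 0.663 with an estimated one. Whether the explants of the groups differed in stage or tissue was not tested. A change in the share of dividing cells and an effect of multicilin on the S phase programme stay open, as no value apart from the pattern itself was used to test them.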
